A study of Mus musculus with 5 samples.

How the data were processed

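RNA from 5 single-cell clones of the mouse osteocytic line Ocy454 was labelled with biotin and measured on 1 Affymetrix array per clone, per the labels' protocols. The deposited values are expression per probe set on the log2 scale. The submitters' processing notes name RMA, affy 1.36.1 and R 2.15.1, with no role or order given. RMA corrects background, brings arrays to 1 distribution and summarises the probes of a probe set, so values are comparable between arrays but not between genes, and a shift shared by most genes of a clone is removed. The sorted values of the 5 arrays differ by at most 0.245. The chip definition, filters and genome build are not given in the sources used here. Of 25206 rows, 14333 (56.9%) hold a value that repeats between arrays and 1430 hold a single value on all 5, a trait of the median-based summary that makes some variances 0.

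Probe sets were named through the platform table, updated by Entrez gene number against a RefSeq gene table of assembly GRCm38.p6, which was used only for names, chromosomes and the order of neighbouring genes. All 23185 probe sets with 1 gene were matched, 0 had several genes, and 2021 unnamed probe sets stayed out of every test. Of 685 entries in the 27 fixed lists, 650 were measured (620 distinct genes) and 35 are not analysed here.

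Clones were grouped by their Sost label into 2 high-Sost and 3 low-Sost clones. With 1 array per clone, the p-values of single genes measure the spread between clones, which holds both clone and culture differences. Each gene was tested with limma 3.58.1 in R 4.3.3 (lmFit with the group, eBayes without trend and not robust, 3 residual degrees of freedom and a prior of 0.70), two-sided, with Benjamini-Hochberg adjustment over 23185 genes and a threshold of 0.05. An exact permutation test of 2 against 3 clones cannot give a p under 0.1. Gene lists were tested with limma's camera with a preset correlation of 0.01, adjusted over 27 lists. Its p-values set a list's members against the other genes, so they measure spread between genes in these clones rather than between clones. Alternatives were camera with a correlation estimated per list and fry, directional and, added after seeing the data, in either direction. With an estimated correlation 0 of the 27 lists passed. The mineralization list's unadjusted camera p rose from 0.00843 to 0.0632, although its estimated correlation was -0.0319, under the preset 0.01. This form rests on the 3 residual degrees of freedom of the fit, fewer with a clone left out, so hardly any list could pass. A call lost there is thus not due to correlation between members alone, and does not show that a difference is absent. This form was not run on simulated data. Folds are powers of 2 of the log2 difference and understate differences of genes near background. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

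Before the data were examined, the tests, the lists and the genes to be named were fixed. Named were a panel of 12 genes and, per direction, up to 12 genes by size among those passing with no overlap between clones. Where fewer passed, this was filled up to 8 by smallest p among genes with an absolute log2 difference of 1 or more and no overlap. From each list up to 4 members that passed were named, or else the 2 with the smallest p. Predicted genes, olfactory and vomeronasal receptors and small RNAs were excluded. The rule named 74 genes, and 37 more were chosen after their values were seen.

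Alternatives fixed beforehand were leaving out the dimmest 30% of genes, shifting arrays to 1 median, quantile normalization again, a variance trend with and without robust settings, array weights, an unmoderated equal-variance test, an adjusted p under 0.1, limma's treat against a log2 difference of 0.5, the other list tests, lists without Sost, and leaving out each clone in turn. Without 12H or 15H the high-Sost group is 1 clone, which is assumed to vary like the low-Sost clones. Averaging probe sets of a gene did not apply, since each gene had 1. Added after seeing the data were an estimated correlation with a clone left out, leaving out genes constant on all arrays, subtracting each clone's chromosome medians, and the counts by unadjusted p and by size. The chromosome medians came from genes with a mean of 6 or more but were subtracted from every gene of the chromosome. Dim genes may be over-corrected in that setting.

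Chromosome shifts used 7807 genes with a mean of 6 or more on chromosomes 1 to 19 and X. Each gene's deviation in a clone from the median of the other 4 was centred on the clone's median, and chromosome medians were tested with 10000 permutations of genes over chromosomes, adjusted over 100 combinations of clone and chromosome. The smallest p these can give is 1e-04. They move genes and not clones, so they do not measure the spread between clones.

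The steps were tested on simulated data with the real means and spreads. For the group comparison with 200 of 23185 genes altered, 31.3% of genes set to differ by 1 on the log2 scale, 68.7% by 2 and 81.8% by 4 passed at an adjusted p under 0.05, along with 10 of 22985 unaltered genes. The altered genes were drawn from all named genes, of which 1280 are constant on all 5 arrays. These shares may thus overstate what the test finds among genes that vary widely between clones. At an unadjusted p under 0.05, 6.15% of unaltered genes passed. With no list raised 0 of 27 lists passed camera. In 100 further runs with no list raised, 1 or more lists passed in 2 with camera, in 7 with directional fry and in 85 with fry in either direction, with genes simulated as independent. With the osteoblast list raised by 1 it had adjusted p = 0.184, and raised by 2 it had adjusted p = 6.5e-10 with 0 of the other 26 passing. Raised by 4, 1 other list passed as well. For the chromosome step on 7807 genes, 0 of 100 combinations passed without a shift. With chromosome 11 raised by 0.2 in 1 clone, 10 passed, of which 9 had shifts of 0.045 or less and the raised one an estimate of 0.189. A minimum shift of 0.1 was therefore added, after the real values had been seen, and counts are given with and without it.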

Results

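Gene expression was measured on 5 Affymetrix arrays, 1 for each of 5 single-cell clones of Ocy454, a mouse osteocyte-like cell line. Per the labels, 37 clones were screened for Sost after 7 days in culture, and 2 clones with the highest Sost (12H and 15H, the high-Sost clones) and 3 clones with low Sost (4L, 9L and 24L, the low-Sost clones) were profiled after 7 days at 37 °C without treatment. Sost encodes sclerostin, a secreted Wnt inhibitor made by osteocytes. The comparison asks which other genes differ between clones chosen for high and for low Sost. Values are RMA log2 expression for 23185 named genes, the array medians lie between 4.04 and 4.08, and the number of arrays limits the precision. Differences are given as high-Sost minus low-Sost clones, with the moderated standard error (SE) and the adjusted p of limma.

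Sost itself (Entrez gene 74499, chromosome 11) read 4.08 in clone 12H and 3.92 in clone 15H, against 3.78 in 4L, 3.89 in 9L and 3.91 in 24L. The group means were 4.00 ± 0.11 (SD, n = 2) and 3.86 ± 0.07 (SD, n = 3), a difference of 0.14 (SE 0.07) or 1.10-fold that did not pass the test (adjusted p = 0.737). Clone 15H exceeded clone 24L by less than the SD of either group. Sost lay at the 45.2 to 49.3 percentile of all named genes in the 5 clones, and above 96.3% to 97.9% of 1354 olfactory and vomeronasal receptor genes, a class expressed mainly in sensory tissue. Sost chose the clones, so its difference is no independent finding.

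Among the panel of osteocyte genes, Dmp1, Phex and Dkk1 had wider differences than Sost, and Mepe, Fgf23 and Tnfsf11, which read low in every clone, did not. Dmp1, a matrix protein of mineralizing osteocytes, averaged 6.60 ± 1.20 (SD, n = 2) in high-Sost and 2.74 ± 0.18 (SD, n = 3) in low-Sost clones, 14.6-fold apart. Phex, an endopeptidase of phosphate homeostasis, was 15.0-fold higher in the high-Sost clones (difference 3.90, SE 0.49), and Dkk1, another secreted Wnt inhibitor, 13.8-fold higher (3.78, SE 0.52). None of the 3 passed over all genes (adjusted p = 0.585 for Dmp1 and 0.572 for both Phex and Dkk1), and their clones did not overlap. Of 22 osteocyte markers measured, these 3 were higher and Pdpn, a podoplanin gene of early osteocytes, was lower (-0.92, SE 0.13) when adjusted over the list alone. The list as a whole did not pass camera (adjusted p = 0.353), with a median difference of 0.08 and a mean of 0.61.

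Mef2c, a transcription factor acting on the Sost enhancer, read 10.1 and 9.73 in the high-Sost clones and 6.80 in 4L, 9.14 in 9L and 8.63 in 24L (difference 1.73, SE 0.84). Pth1r, the receptor for parathyroid hormone, read 9.20 and 8.99 against 4.23 in 4L and 7.69 in both 9L and 24L (difference 2.55, SE 1.34, adjusted p = 0.737). Mepe, Fgf23 and Tnfsf11 read between 2.79 and 3.69 in every clone, with differences of -0.02, -0.05 and 0.02. The 95th percentile of the receptor genes lay between 3.37 and 3.56 over the clones. Mepe and Fgf23 stayed under it in every clone, and Tnfsf11, at 3.62 to 3.69, lay little above it. At such levels, lack of a difference in these genes cannot be told from lack of signal. Tnfrsf11b, the decoy receptor for RANKL, differed by -0.56 (SE 0.80), Hdac4 by -0.21 (SE 0.28) and Hdac5 by 0.02 (SE 0.14). The last 2 encode class IIa histone deacetylases that bind MEF2 factors.

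**Figure D1:**
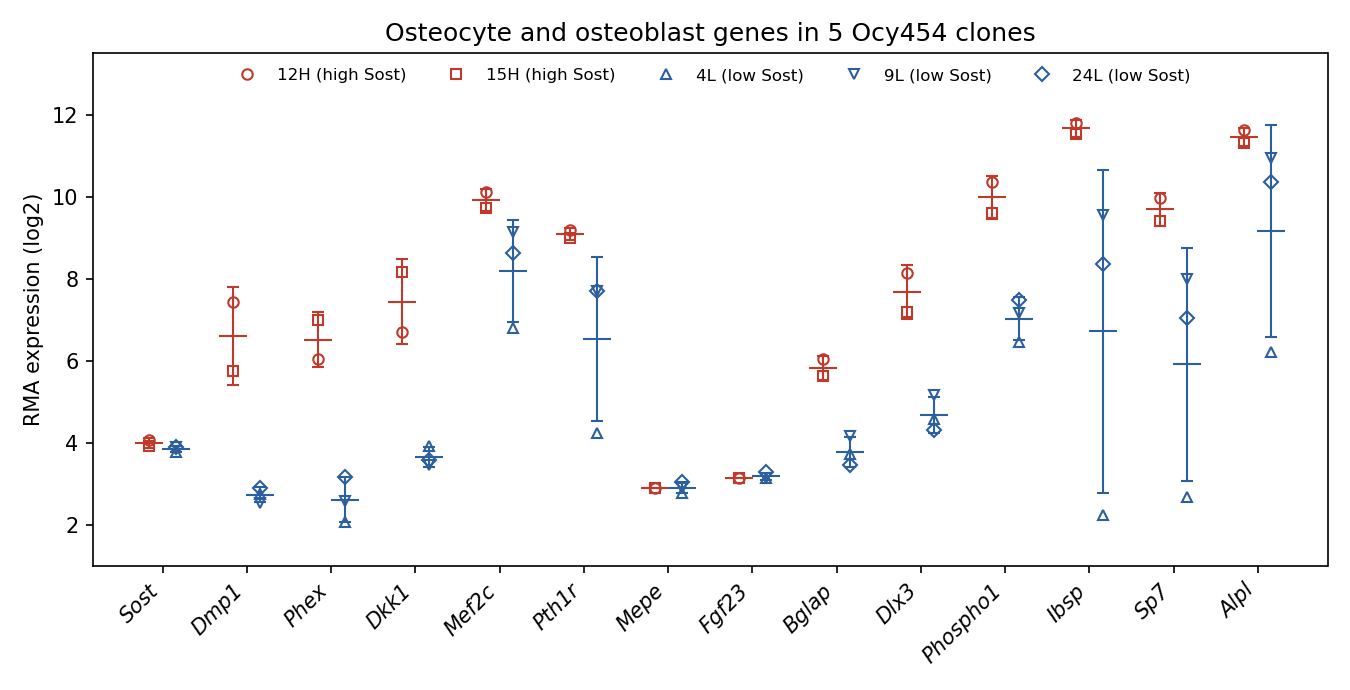
RMA log2 expression (vertical axis) of 14 osteocyte and osteoblast genes in each clone (points; red, high-Sost; blue, low-Sost), with group means and SD (bars). Dmp1 stands at 7.45 and 5.75 in the high-Sost clones and at 2.90 or less in the low-Sost clones, while Sost stands between 3.78 and 4.08 in all 5.

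Among all genes, Spns2, a sphingosine-1-phosphate transporter, read 8.33 ± 0.15 (SD, n = 2) in high-Sost and 4.93 ± 0.07 (SD, n = 3) in low-Sost clones, 10.6-fold apart. Megf10, an engulfment receptor, was 12.7-fold higher in the high-Sost clones (3.66, SE 0.11). Emc2, a subunit of the endoplasmic reticulum membrane complex, was lower in them by a difference of -1.03 (SE 0.03). These 3 genes had the smallest adjusted p, 0.0856 each. No gene passed limma's test at an adjusted p under 0.05 (0 higher, 0 lower, and so 0 with a 2-fold or larger difference). At an unadjusted p under 0.05, 712 genes were higher and 628 lower in high-Sost clones, 5.78% of those tested. In simulated data 6.15% of unaltered genes fell under that limit. Those genes were drawn independently, so this share is not a chance rate for these clones. Among splits of the clones into 2 and 3, the real one gave 1340 genes. The split of 4L with 24L against the rest gave 1463, and the others gave 441 to 927. For the real split, an unmoderated equal-variance test gave 461 higher and 406 lower. Without clone 15H the counts were 1816 and 1289, and without 12H 1098 and 1008. By size, 201 genes were at least 2-fold higher and 228 at least 2-fold lower with no overlap between clones, against 348 and 472 without clone 15H and 302 and 377 without 9L, where fewer clones make non-overlap easier. Without regard to size 16% of genes had no overlap. The mean over all 10 splits of the clones into 2 and 3 was 11.3%, since tied values hold it under the 20% of untied data, and the highest other split gave 16.3%. With the 2-fold limit added, the real split gave 429 genes and 4L with 24L against the rest gave 451.

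The other genes with the smallest p among those at least 2-fold higher did not pass either. They were Metrnl, a secreted factor (1.66, SE 0.08), Ptch1, the hedgehog receptor (1.75, SE 0.08), Carmil1 (1.19, SE 0.13), Bcl7a (1.27, SE 0.14), Ripor2 (1.40, SE 0.17) and Adam12, a metalloprotease (2.57, SE 0.32). Their adjusted p lay between 0.258 for Metrnl and Ptch1 and 0.572.

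Genes lower in the high-Sost clones, which likewise did not pass, included some of the widest gaps. Ccn3, a matricellular protein, averaged 4.46 ± 1.11 (SD, n = 2) against 10.1 ± 0.78 (SD, n = 3), 50.6-fold lower. Robo2, a receptor for Slit ligands, averaged 2.49 against 7.30, 28.1-fold lower. Cav1 and Cavin4, both of caveolae, differed by -2.22 (SE 0.22) and -1.03 (SE 0.10). Fgf21, a hormone of metabolic stress, differed by -1.93 (SE 0.15), Casp4, an inflammatory caspase, by -2.40 (SE 0.26) and Dclk1 by -1.36 (SE 0.15). Adjusted p ran from 0.465 for Fgf21 to 0.572 for Ccn3. Robo2 and Cav1 passed when adjusted over the list alone, within 41 axon guidance and 26 mechanosensing genes.

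**Figure D2:**
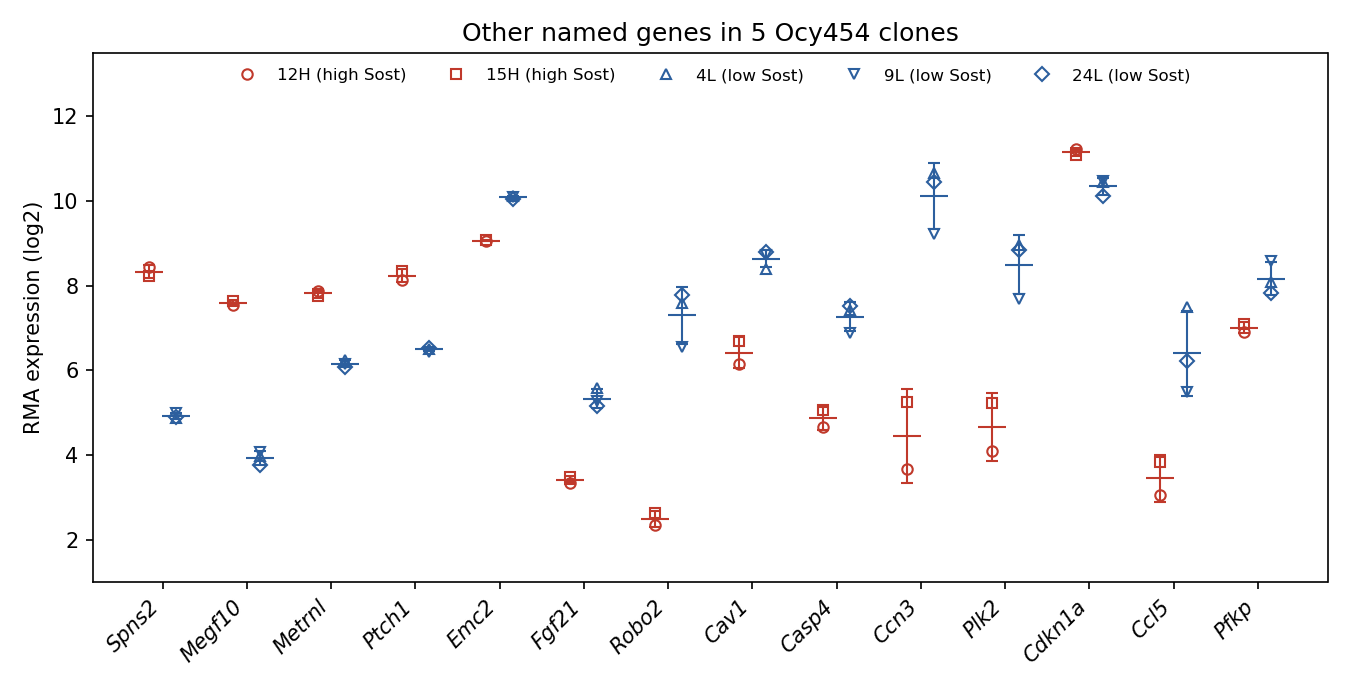
RMA log2 expression (vertical axis) of 14 other named genes in each clone (points; red, high-Sost; blue, low-Sost), with group means and SD (bars). Spns2 averages 8.33 in the high-Sost and 4.93 in the low-Sost clones, and Ccn3 stands at 5.25 or less against 9.23 or more.

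Osteoblast markers were higher in the high-Sost clones as a list (camera with a preset correlation of 0.01, adjusted p = 0.00465), with a median difference of 1.51 over 18 measured members. The call was lost with an estimated correlation (adjusted p = 0.948), where 0 of the 27 lists passed, and with the directional fry test (adjusted p = 0.546). The estimated-correlation form has few degrees of freedom. A loss there, for this list and those below, cannot tell absence of a difference from too few clones. Over all genes 0 members passed, and 3 were higher adjusted over the list alone. They were Bglap, which encodes osteocalcin (2.04, SE 0.28), the transcription factor Dlx3 (2.99, SE 0.43) and Phospho1, a phosphatase that starts mineral formation (2.95, SE 0.44). By size, 9 members were at least 2-fold higher and 1, Omd (-2.31, SE 0.84), at least 2-fold lower without overlap. Ibsp, Sp7 and Alpl, taken up after their values were seen, differed by 4.94 (SE 2.64), 3.78 (SE 1.91) and 2.29 (SE 1.73). Clone 4L read 2.24 for Ibsp and 2.68 for Sp7, where 24L, the next lowest clone, read 8.35 and 7.05. Without clone 12H the list's adjusted p was 0.0839, without clone 15H 0.0583, and without clone 4L 0.00155 with a median of 0.65 (adjusted p = 0.899 with an estimated correlation in that fit).

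Mineralization and phosphate genes stood just outside the threshold (adjusted p = 0.0569, 21 measured, median 0.42). Phex, Phospho1 and Dmp1 were higher adjusted over the list alone. They are also members of the osteocyte list (Phex and Dmp1) or the osteoblast list (Phospho1), and so are no separate support. By size 8 members were at least 2-fold higher, among them Smpd3 (3.05, SE 0.93) and Galnt3 (2.38, SE 0.72), and 1 was lower, Mgp, an inhibitor of mineralization (-2.13, SE 0.72); these last 3 were taken up after their values were seen. The directional fry test placed the list past the threshold (adjusted p = 0.0192), as did camera without the dimmest 30% of genes (0.0358), with arrays shifted to 1 median (0.0191), with quantile normalization again (0.0344), without clone 4L (0.0292) and, in settings chosen after the data were seen, without constant genes (0.0143) and with chromosome shifts subtracted (0.00246). Camera left the list outside the threshold with a variance trend (adjusted p = 0.0554) and with array weights (0.0540). It did so too with any clone other than 4L left out (0.112 without 9L and 0.137 without 24L). With an estimated correlation camera gave adjusted p = 0.862, and 0.899 without clone 4L.

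Inflammatory and chemokine genes were lower in the high-Sost clones as a list (camera adjusted p = 0.0228, 27 measured, median -0.40). The call was lost with an estimated correlation (adjusted p = 0.948) and with directional fry (adjusted p = 0.538). By size 9 members were at least 2-fold lower and 0 higher without overlap, and 0 passed over all genes or over the list alone. Ccl5 averaged 3.45 ± 0.55 (SD, n = 2) against 6.40 ± 1.01 (SD, n = 3), a difference of -2.95, and Ccl9 differed by -1.36 (SE 0.40). Ccl2 (-2.67, SE 0.84), Ccl7 (-2.58, SE 1.00), Cxcl12 (-1.63, SE 0.50) and the adhesion molecule Vcam1 (-2.39, SE 1.15), taken up after their values were seen, had the same direction. The list's adjusted p was 0.379 without clone 12H, 0.116 without 15H and 0.0881 without 24L.

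Hypoxia and glycolysis genes were also lower as a list (camera adjusted p = 0.0139, 25 measured, median -0.41), a call lost with an estimated correlation (adjusted p = 0.948) and with directional fry (adjusted p = 0.625). The list had 2 members at least 2-fold lower without overlap and 0 passing over all genes or the list alone. Pfkp, a phosphofructokinase, differed by -1.16 (SE 0.27) and Ddit4, a stress-induced inhibitor of mTORC1, by -0.89 (SE 0.20). Slc2a1, the main glucose transporter (-0.96, SE 0.35), and Egln3, an oxygen sensor (-1.24, SE 0.48), were taken up after their values were seen. The list mean stood highest in clone 9L, 0.54 above the mean of the 5 clones, at 0.15 in 24L, and at -0.25 in 12H, -0.23 in 15H and -0.21 in the low-Sost clone 4L, which lay level with the high-Sost clones. The list's adjusted p was 0.2 without clone 9L, 0.0839 without 12H and 0.121 without 15H, and 4.99e-07 without clone 4L (adjusted p = 0.899 with an estimated correlation in that fit).

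**Figure D3:**
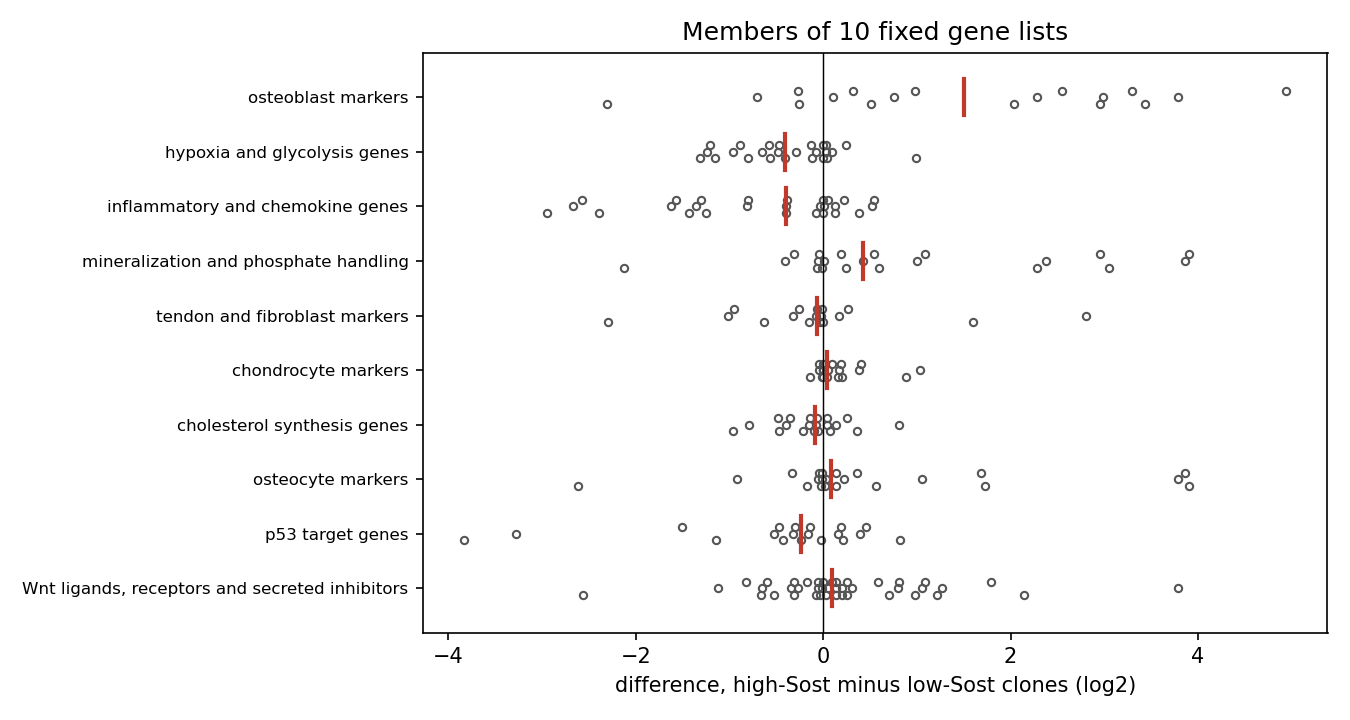
Differences between high-Sost and low-Sost clones (horizontal axis, log2) for the members (circles) of the 10 fixed gene lists with the smallest camera p, with each list's median (red bar). The median of the osteoblast markers is 1.51, and those of the hypoxia and the inflammatory lists are -0.41 and -0.40.

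Neither of the Wnt lists passed camera (adjusted p = 0.401 and 0.638), and 0 members of either passed over all genes or adjusted over the list alone, so members are given as values. Among 41 Wnt ligands, receptors and inhibitors, Wif1, a secreted Wnt inhibitor, differed by 2.14 (SE 0.36) and Dkk1 by 3.78, while Rspo2, a secreted amplifier of Wnt signals, differed by -2.56 (SE 0.50). Of 23 Wnt/beta-catenin target genes, Axin2, a feedback inhibitor, differed by -1.25 (SE 0.26), and the R-spondin receptors Lgr5 and Lgr6 by -2.26 (SE 0.69) and 2.39 (SE 0.52). Rspo2, Lgr5 and Lgr6 were taken up after their values were seen.

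In the p53 target list (19 measured, camera adjusted p = 0.399), 3 members passed adjusted over the list alone. Plk2, a polo-like kinase, averaged 4.67 against 8.50 (-3.83, SE 0.61), and Btg2, an antiproliferative factor, differed by -1.15 (SE 0.20). Cdkn1a, the p21 inhibitor of the cell cycle, was higher by 0.82 (SE 0.14). Cell cycle genes did not pass (34 measured, median 0.20, adjusted p = 0.456), with Ttk at -0.33 (SE 0.06) and Tyms at -0.51 (SE 0.22). Without clone 9L the cell cycle list had adjusted p = 0.0330, in the direction of the high-Sost clones, and adjusted p = 0.965 with an estimated correlation in that fit. The list mean stood at -0.51 in 4L, 0.05 in 24L and 0.21 in 9L, against 0.26 in 12H and -0.01 in 15H, so 24L lay above 15H.

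Signalling lists tied to Sost in osteocytes did not pass camera. MEF2, class IIa HDAC and salt-inducible kinase genes had a median of 0.02 (18 measured, adjusted p = 0.931), with Hdac7 at -0.67 (SE 0.14) and Mef2d at 0.68 (SE 0.18). PTH and cyclic AMP response genes had a median of 0.01 (26 measured, adjusted p = 0.931), with Pde4d at 0.69 (SE 0.18) and Crem at -0.33 (SE 0.12). TGF-beta and BMP genes had a median of 0.06 (42 measured, adjusted p = 0.842) and a mean of -0.04, with Tgfb1 at 0.48 (SE 0.08) and Bmp1 at 1.17 (SE 0.23). Notch pathway genes had a median of -0.09 (17 measured, adjusted p = 0.638), with Hey1 at 0.75 (SE 0.23) and Lfng at -0.83 (SE 0.31).

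The matrix lists did not pass camera, with 0 members of the collagen and the perilacunar list passing over all genes or the list alone. Fibrillar collagen and matrix assembly genes (33 measured, adjusted p = 0.931) held Loxl4 at 1.47 (SE 0.37) and Loxl1 at -1.88 (SE 0.56), both lysyl oxidases that cross-link collagen, and Col3a1, taken up after its values were seen, at -2.66 (SE 1.29). Perilacunar remodelling genes (18 measured, adjusted p = 0.713) held Mmp14, a membrane collagenase, at 0.50 (SE 0.08) and Slc4a2 at 0.36 (SE 0.10). Axon guidance genes (median 0.02, mean -0.09, camera downward) and mechanosensing genes (median 0.01, mean -0.01, camera downward) had adjusted p = 0.842 and 0.931, with Sema7a at 1.35 (SE 0.30) and Cnn1, a smooth muscle calponin, at -2.89 (SE 0.79).

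Markers of other cell types did not pass camera as lists. Tendon and fibroblast markers had adjusted p = 0.0936 (17 measured), with Egr1 at -0.95 (SE 0.15) and S100a4 at -0.63 (SE 0.13). Chondrocyte markers had adjusted p = 0.108 (20 measured), with Col11a2 at 1.03 (SE 0.21) and Sox6 at 0.88 (SE 0.28), and 1 of them averaged 6 or more. Muscle and smooth muscle markers had adjusted p = 0.615, with Acta1 at 0.48 (SE 0.10), and the contractile genes Tagln and Acta2, taken up after their values were seen, at -1.78 (SE 0.72) and -1.30 (SE 0.41). Adipocyte markers had adjusted p = 0.823 (median -0.001, mean 0.23, camera upward), with Car3 at 3.44 (SE 0.92) and Scd1 at 0.21 (SE 0.11). Of 15 blood and endothelial markers (adjusted p = 0.931) 0 averaged 6 or more, Fcer1g differed by 0.33 (SE 0.17) and Cd3e by 0.19 (SE 0.13). The 7 Y-linked genes (adjusted p = 0.456) also averaged under 6, with Usp9y at 0.10 (SE 0.07) and Zfy1 at 0.35 (SE 0.25).

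The stress and metabolic lists left did not pass camera either. Interferon response genes had adjusted p = 0.527 (25 measured), with Cxcl10 at -1.25 (SE 0.56) and Irf9 at 0.65 (SE 0.38). Without clone 12H, which leaves 15H as the lone high-Sost clone with its spread taken from the low-Sost clones, the list had adjusted p = 3e-05, and adjusted p = 0.988 with an estimated correlation in that fit. Unfolded protein response genes had adjusted p = 0.817, with Atf3 at -0.78 (SE 0.18) and Chac1 at -0.84 (SE 0.33). Without clone 9L that list had adjusted p = 0.0258, upward, and adjusted p = 0.965 with an estimated correlation in that fit. Cholesterol synthesis genes had adjusted p = 0.308, with Cyp51 at -0.96 (SE 0.16) and Dhcr7 at 0.81 (SE 0.37). Hox cluster genes had adjusted p = 0.504, with Hoxc5 at 0.46 (SE 0.11) and Hoxa4 at 0.53 (SE 0.15).

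A second fry test, chosen after the data were seen, asks whether members of a list differ in either direction and does not compare the list with other genes. It placed 9 of the 27 lists past the threshold. They were osteocyte markers and mineralization genes (adjusted p = 0.00209 each), Wnt ligands, receptors and inhibitors (0.0155), Wnt/beta-catenin targets and tendon and fibroblast markers (0.0171 each), mechanosensing genes (0.0233), osteoblast markers and p53 targets (0.0275 each) and muscle markers (0.0357). The inflammatory and the hypoxia list did not pass it (0.0684 and 0.145). In simulated data with no list altered it placed 1 or more lists past the threshold in 85 of 100 runs, and at most 7, so no single list is called from it.

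Genes of single chromosomes moved together in single clones. On chromosome 15, the 347 genes with a mean of 6 or more had a median of -0.36 in clone 12H of 0.30 in 4L and of 0.27 in 9L, each against the other 4 clones, and of -0.12 in 15H and -0.05 in 24L. The high-Sost clone 15H and the low-Sost clone 24L thus lay close together. The median difference between the groups was -0.33 relative to all such genes, and was not tested against the spread between clones. At an unadjusted p under 0.05, 83 of the 873 tested chromosome 15 genes were lower and 15 higher, and 31 lower and 146 higher with chromosome shifts subtracted. The shifts came from the 347 genes but were subtracted from all 873. Dim genes may thus be over-corrected, and the reversal is not read as a result. Emc2 and Ccn3 lie on this chromosome. On the X chromosome the median was -0.40 in clone 12H, on chromosome 6 it was 0.36 in 12H, and on chromosome 1 it was -0.31 in 4L. These medians were computed after the data had been seen.

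**Figure D4:**
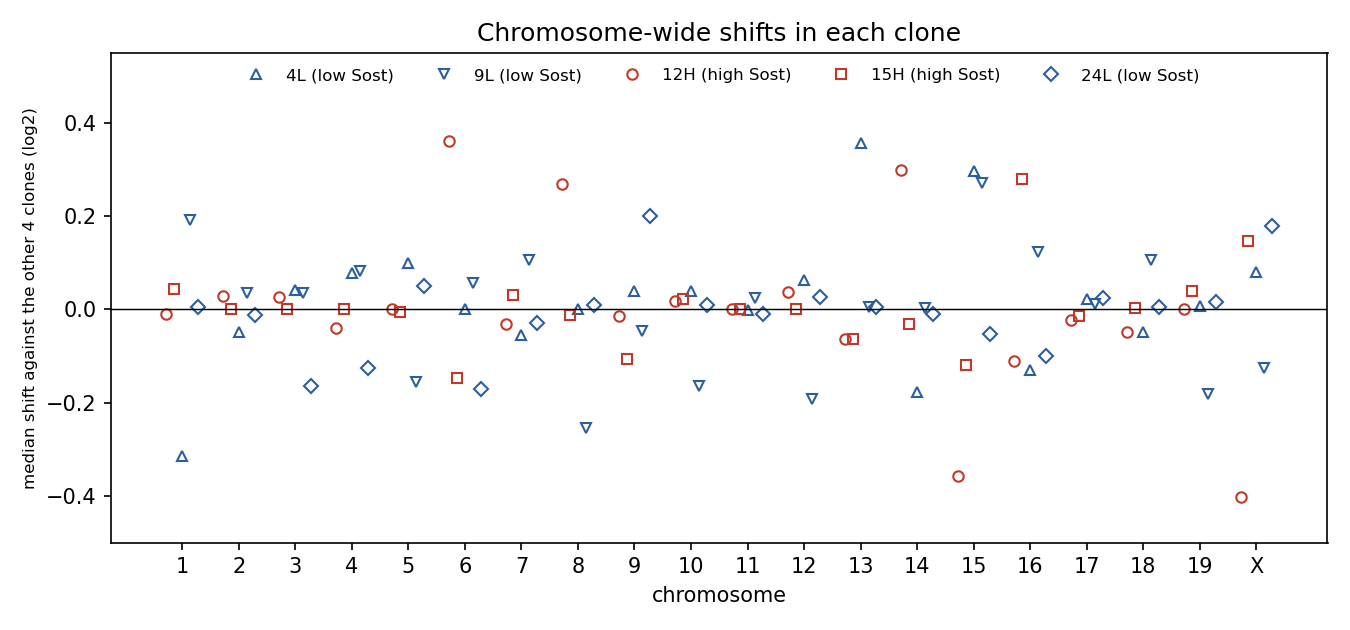
Median shift of each clone against the other 4 (vertical axis, log2) over the genes with a mean of 6 or more on each of 20 chromosomes (horizontal axis); red symbols are high-Sost and blue symbols low-Sost clones. The lowest point is clone 12H on chromosome X at -0.40 and the highest is clone 12H on chromosome 6 at 0.36.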

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

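Counts by unadjusted p and by size, and the settings on constant genes, chromosome medians and fry in either direction, were chosen after the data were seen. The counts of 0 genes past an adjusted p under 0.05 became 2 higher (Spns2 and Megf10), both at least 2-fold, with arrays shifted to 1 median, without genes constant on all arrays and with chromosome shifts subtracted, and 2 higher and 1 lower at an adjusted p under 0.1. They stayed at 0 under the other settings run, treat against 0.5 and each clone left out included. At an unadjusted p under 0.05 the 712 higher and 628 lower genes became 461 and 406 with the unmoderated test, and with 1 clone left out ran from 633 to 1816 and from 640 to 1289, highest without 15H (1098 and 1008 without 12H). By size without overlap, 201 higher and 228 lower ran from 163 to 348 and from 212 to 472, highest without 15H (302 and 377 without 9L), where fewer clones make non-overlap easier. The 3 lists past the threshold became 0 with an estimated correlation, and 4, with the mineralization list added, without the dimmest 30% of genes, with arrays shifted to 1 median, with quantile normalization again, without constant genes and with chromosome shifts subtracted. With directional fry 0 of these 3 passed and 1 other did, the mineralization list, and 9 lists passed with fry in either direction, the osteoblast list among them and the other 2 not. With 1 clone left out 0 to 4 lists passed, with 0 without 15H and 1 without 12H, the interferon list, which is not one of the 3. Apart from the effect of fewer clones on overlap, the cause was not tested. The Sost difference of 0.14 lay between 0.06 without 12H and 0.22 without 15H and passed in no setting. Over 111 named genes, 7 of 1552 values had another sign than with all clones and the main settings, in Bst2, Hdac4, Hdac5, Mepe, Stat2 and Tnfsf11. Genes near background allow no firm reading of small differences.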

Other observations

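Chosen only after the result was seen were the tests of Sost against receptor genes and over the splits of the clones, the permutation, block and change-of-level tests of chromosomes, the subtraction of chromosome shifts, the osteoblast list's median without 4L and the use of its planned p there to weigh that clone, fry in either direction, an estimated correlation with a clone left out, and the counts over splits and of genes per clone; the genes named in the next paragraphs were also chosen after their values were seen.

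Some genes with wide differences and no overlap lie outside the fixed lists, and none of those introduced here passed limma's test over all genes (adjusted p between 0.465 and 0.737). Aspn, which encodes asporin, a small matrix proteoglycan, read 1.76 and 3.53 in 12H and 15H against 7.57, 7.81 and 10.5 in 4L, 9L and 24L. Igfbp2, a binding protein for insulin-like growth factors, differed by -3.55 (SE 0.81) and Tgfbi, a matrix adhesion protein, by -3.49 (SE 0.81). Srpx2 (4.83, SE 0.71), the surface glycoprotein Cd200 (4.00, SE 0.80) and the amino acid transporter Slc36a2 (3.32, SE 0.44) were higher in the high-Sost clones. Gli1, a transcription factor induced by hedgehog signals, differed by 0.92 (SE 0.08) in the direction of Ptch1 (1.75). In the low-Sost clones Gli1 read 3.31 to 3.49, about the 95th percentile of receptor genes (3.37 to 3.56). Hedgehog signalling was not tested as a list.

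The low-Sost clones were not alike. Clone 4L had 199 genes at least 2-fold below all 4 other clones and 124 above them, against 24 and 55 for 9L and 19 and 87 for 24L. Besides Ibsp and Sp7, 4L read 2.69 for Panx3, a channel of osteoblasts, where the others read 7.57 to 10.9, and 5.17 for Tmem119, an osteoblast differentiation factor, where the others read 8.91 to 10.3. Cdh11, osteoblast cadherin, read 6.19 in 4L and 10.5 to 11.3 in the others. Clones 12H and 15H differed in interferon response genes, whose list mean lay 0.53 below the 5-clone mean in 12H (-0.53) and 0.73 above it in 15H. Irf7 read 6.73 in 12H and 8.11 in 15H, Stat2 6.62 and 7.97, Bst2 8.74 and 10.1, Oas2 3.83 and 5.60, and Usp18 5.95 and 7.03. At least 2-fold apart were 460 genes between 12H and 15H, 474 between 9L and 15H and 1444 between 4L and 12H.

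Sost differed by 0.14 between clones chosen for it. A probe set that responds poorly near background may hide a difference, and the tables do not decide this: the lower of the high-Sost clones stood above 97.1% of receptor genes, between the limits of 95 and 99 set for the test. Exchanged labels stay open for the same reason. The labelled split had the largest absolute Sost difference of the 10 splits of the clones into 2 and 3, 0.137 in the labelled direction. Close to it stood 4L with 9L (-0.134) and 12H with 24L (0.132), so this lead does not bear on the labels. A probe set that does not respond could give no difference in any split. Dmp1, Phex and Dkk1 were 14.6-, 15.0- and 13.8-fold higher in the clones labelled high, but the labels rest on Sost and not on these genes. Sost RNA that was in truth alike in these cultures at harvest was not tested and stays open.

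Chromosome-wide shifts were seen in every clone. Chance placement of clone-specific genes is argued against, as 72 of 100 combinations of clone and chromosome passed the permutation test, 32 of them with a shift of 0.1 or more. Normalization that depends on intensity is argued against too, but only among the genes with a mean of 6 or more, since dimmer genes were not examined. In 72.2% of the 72, each level class of these genes (low, middle and high) kept at least 50% of the shift (90.6% of the 32). Blocks of 20 neighbouring genes had the sign of their chromosome in 87.1% of cases (98.3% for the 32). The blocks hold the genes that set the chromosome's median, so part of this agreement was built in. In 4L, blocks of chromosome 9, which passed with a shift of 0.04, ran from -0.31 to 0.32. A candidate explanation is a difference in copy number of whole chromosomes between clones, a hypothesis without DNA data. Clone 15H changed level within chromosome 6, from a median of 0.00 over 161 genes up to Suclg1 to -0.31 over 216 genes from Gcfc2 on, the point being chosen on the same values (permutation p = 0.000999, the smallest that 1000 permutations of gene order can give).

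The higher osteoblast list may rest in part on clone 4L. Without it the median difference was 0.65 against 1.51, under 50%, while the list kept its call in camera with a preset correlation (adjusted p = 0.00155). The call was lost with an estimated correlation (adjusted p = 0.948 with all clones and 0.899 without 4L), with directional fry (adjusted p = 0.546), without 12H (0.0839) and without 15H (0.0583). Chromosome shifts were too small to be the source of most of it, the widest between the groups being -0.33 on chromosome 15. The median of 1.43 once they were subtracted therefore adds no separate evidence. A biological difference between clones with high and low Sost remains open and was not tested apart from clone identity.

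For the same list, the 10 splits of 5 clones are too few for a share under 0.05: 2 of the 10 gave an adjusted list p as small, the real one (0.00465) and 4L with 9L against the rest (0.00273, list lower). The list also passed in 3 further splits, 5 of the 10 in all, and 5 other splits put more lists past the threshold than the 3 of the real split, at most 6. With fry in either direction 9 lists passed in the real split and at most 4 in another. Likewise 2 of the 10 gave as many genes at an unadjusted p under 0.05, with 1340 in the real split and 1463 for 4L with 24L against the rest.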
